A study of Mus musculus with 26 samples.

How the data were processed

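RNA was measured in neurons sorted by fluorescence from dissociated dorsal root ganglia of adult reporter mice. Per the labels, RNA was amplified with a NuGEN kit and made into Illumina TruSeq libraries. Nonpeptidergic nociceptors carried MrgD-EGFP, peptidergic nociceptors CGRP-GFP, C-LTMRs ThCreER with Ai14, Aδ-LTMRs TrkBCreER with Ai14, Aβ RA-LTMRs Npy2r-GFP, and proprioceptors PVIRESCre with Ai14. Aβ SA1- and Aβ Field-LTMRs carried TrkCCreER with a GFP allele of Ret and differed in the day and dose of tamoxifen. C-LTMRs also had it after birth, Aδ-LTMRs before and the others none, so it cannot be separated from subtype. The submitters' notes name STAR, HTSeq 0.6.1, DESeq2 1.14.1, Cuffdiff and FastQC 0.11.3 on the mm10 build, with no role stated.

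The authors deposited a table of raw counts per Ensembl gene, a table of regularized log2 values named rlog, and a table of RPKM, each with 26 libraries. An alignment summary deposited by the authors gives GC content in percent, exonic, intronic, intergenic, ribosomal, mapping and duplicate shares as a fraction, the 5' to 3' bias as a ratio whose direction is not stated, mapped reads as counts, and the range of read lengths. The count table held 39017 genes, of which 38828 took a symbol from the RPKM table, 180 from a gene name table and 9 kept the identifier alone. GENCODE release 21 of the mouse gave a position for 37693 genes and none for 1324. Mapped reads ran from 19180452 to 106084755 per library. The exonic share ran from 45.7% in Aβ RA-LTMR library 5 to 82.9% in Aβ SA1-LTMR library 1, the duplicate share from 59.0% to 76.9%, and the mapping rate from 61.4% in Aδ-LTMR library 1 to 97.7%. The 10 most abundant genes took 17.9% to 40.2% of the counts, and the repeat-rich gene Gm26924 0.224% to 7.23%. Between libraries of one subtype, the variance of genes with at least 10 counts was at least 8.56 times what counting alone gives, so the spread between libraries, not depth, set the error of abundant genes.

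The tests used the deposited counts in R 4.3.3 with edgeR 4.0.16: filterByExpr with the 8 groups left 17411 genes, TMM set the library factors, and estimateDisp and a robust glmQLFit gave the quasi-likelihood fit. The common dispersion was 0.107, a coefficient of variation of 0.327, with a median of 7.01 prior degrees of freedom. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Each SE is the log2 fold change divided by the root of its F statistic. The comparisons were an F test over the 8 subtypes, each subtype against each of the other 7, the mean of the 5 A-fibre subtypes against the mean of nociceptors and C-LTMRs, 3 planned pairs, and all 28 pairs. CPM were counts scaled to the library total after TMM, and log2 CPM used a prior count of 2. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 42 lists, and again with an estimated correlation. Mean log2 CPM of 11 lists of other cell types, stress, injury, sex and mitochondria was compared over subtypes with 100000 resamples of the labels. DESeq2 1.42.0 served as another test, and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 made the scores and figures.

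Groups, tests, lists, most alternatives and the rule for naming genes were set before the data were examined. The lists were Kv alpha and accessory subunits, two-pore-domain, calcium- or sodium-activated and inward-rectifier potassium channels, sodium, calcium, HCN, TRP, mechanotransduction and acid-sensing, chloride, and purinergic and cholinergic channels, and GABA-A and glycine, ionotropic glutamate, modulatory and Mas-related receptors. Others held neuropeptides, neurotrophic receptors, neurofilaments, transcription factors, vesicular transporters, oxidative phosphorylation, ribosomal proteins, adhesion and guidance, labelling genes and markers of 6 subtypes. The rest held genes of satellite glia, Schwann cells, macrophages, endothelial cells, fibroblasts, pericytes, erythroid cells, stress, axon injury, sex-linked and mitochondrially encoded genes. The rule names labelling genes, the 4 enriched genes of each subtype with the largest smallest difference at a mean of 5 CPM or more, and the 10 genes with the largest fold in each direction of the other comparisons at 5 CPM or more with no overlap between libraries. It also names list members with the largest fold past the threshold or, for ion channels, those enriched in a subtype, and not all of these are printed. Some genes that the rule selects are not reported here. Symbols of the form Gm plus digits or ending in Rik were not named. No fold is given against a group with 0 counts, and genes with 1 to 3 counts in the lower group were passed over, except Fam26d, which is given as a ratio. Htr2c, Tek, F2rl1, Mafa, Etv4 and Sst were passed over in pairs for this reason. Amplified pools of sorted neurons give relative RNA levels, not protein or copies per cell.

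The procedure was tested on simulated counts with 200 changed genes, 50 at each of 4 folds. Of genes raised in Aβ SA1-LTMRs alone, 66%, 84%, 94% and 96% were called at folds of 3, 4, 8 and 16, with 0 false calls among 16844. For Aβ RA-LTMRs the shares were 62%, 82%, 96% and 100%, with 0 among 16771. False calls of genes that several subtypes share were not tested. Every gene raised in A-fibre types was called, with 3 false calls among 16916, and Aβ SA1- against Aβ Field-LTMRs gave 88%, 86%, 98% and 98%, with 2 among 16912. Alternatives set beforehand were DESeq2's size factors, the DESeq2 Wald test, no filter, no minimum fold, limma on the rlog values and on log2 RPKM with a pseudocount of 1 or 0.1, and thinned counts. Others were the satellite glia score as a covariate, a block for the replicate number, only the libraries of the compared pair, no Aβ RA-LTMR libraries 4 and 5, no peptidergic nociceptors or no proprioceptors in the A-fibre comparison, and each library left out in turn. 5 further alternatives were chosen after seeing the data: read-length class, exonic share and endothelial score as covariates, no libraries under 60% exonic reads, and no mt-Rnr1, mt-Rnr2 and Gm26924.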

Results

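Messenger RNA was sequenced from 8 subtypes of fluorescently labelled dorsal root ganglion neurons of adult mice, at postnatal day 23 or later. The subtypes were nonpeptidergic nociceptors, peptidergic nociceptors, and 5 classes of low-threshold mechanoreceptor (LTMR): C-LTMRs, Aδ-LTMRs, and the rapidly adapting (RA), slowly adapting type 1 (SA1) and field Aβ-LTMRs. Proprioceptors, the muscle afferents, made the last group. There were 5 libraries of Aβ RA-LTMRs and 3 of every other subtype, 26 in all, and each library pooled neurons of several mice and sorting rounds. Ganglia came from all axial levels, except that proprioceptors came from thoracic ganglia alone. The total count per library ran from 10706522 in Aβ Field-LTMR library 2 to 66309214 in C-LTMR library 3. The mitochondrial ribosomal RNA genes mt-Rnr1 and mt-Rnr2 took 12.2% of the counts in nonpeptidergic nociceptor library 2 and 28.4% in Aβ RA-LTMR library 2. Gene levels are counts scaled to library size (CPM), as mean ± SD over the libraries of a subtype, with n = 3 libraries, or n = 5 for Aβ RA-LTMRs. Each log2FC is a log2 fold change from edgeR's quasi-likelihood test with its SE, and its adjusted p is the Benjamini-Hochberg value over the 17411 genes tested. A gene is called enriched in a subtype when it passed against each of the other 7, and the smallest of the 7 differences is printed with the largest of the 7 adjusted p. Coordinates are of the mm10 build.

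The genes whose regulatory elements drove the reporters were read first, since they check the labels. Mrgprd, the receptor that marks nonpeptidergic nociceptors (chromosome 7, 145314835 to 145324086), stood at 1026 ± 195 CPM in them and was enriched over every other subtype (log2FC 3.95, SE 0.64, adjusted p = 3.6e-05 against peptidergic nociceptors). Calca, which encodes the peptide CGRP (chromosome 7, 114631478 to 114636357), stood at 3556 ± 289 CPM in peptidergic nociceptors (log2FC 2.61, SE 0.60, adjusted p = 0.00324 against C-LTMRs). Th, the tyrosine hydroxylase gene (chromosome 7, 142892752 to 142931128), stood at 398 ± 57.1 CPM in C-LTMRs (log2FC 3.81, SE 0.46, adjusted p = 9.2e-07 against peptidergic nociceptors). Pvalb, encoding the calcium buffer parvalbumin (chromosome 15, 78191114 to 78206400), stood at 281 ± 78.0 CPM in proprioceptors (log2FC 2.41, SE 0.40, adjusted p = 1.0e-04 against Aβ SA1-LTMRs). Ntrk2, the TrkB receptor gene (chromosome 13, 58806569 to 59133970), was as high in Aβ RA-LTMRs, at 439.6 ± 20.9 CPM, as in Aδ-LTMRs, at 523 ± 112 CPM (log2FC 0.25, SE 0.19, adjusted p = 0.377). It passed against each of the other 6 subtypes. With the satellite glia score as a covariate Mrgprd and Th kept their calls, while Calca (log2FC 2.56, adjusted p = 0.134) and Pvalb (log2FC 0.97, adjusted p = 0.415) missed the threshold. Ntrk3, the TrkC receptor gene (chromosome 7, 78175959 to 78738012), stood at 194 ± 28.5 CPM in Aβ SA1-LTMRs and 195 ± 88.9 CPM in Aβ Field-LTMRs, which carry the same alleles. In proprioceptors Ntrk3 stood at 110.5 ± 38.4 CPM, and their difference from Aβ SA1-LTMRs did not pass (log2FC -0.81, SE 0.33, adjusted p = 0.0672). Npy2r, the neuropeptide Y receptor gene of the Aβ RA-LTMR reporter (chromosome 3, 82538383 to 82548084), was highest in peptidergic nociceptors, at 52.9 ± 4.99 CPM, against 20.4 ± 5.01 CPM in Aβ RA-LTMRs (log2FC -1.38, SE 0.61, adjusted p = 0.0738). Ret, whose reporter allele was combined with TrkC for Aβ SA1- and Field-LTMRs, was highest in C-LTMRs, at 1356 ± 64.6 CPM, and nonpeptidergic nociceptors, at 1231 ± 31.0 CPM.

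**Figure D1:**
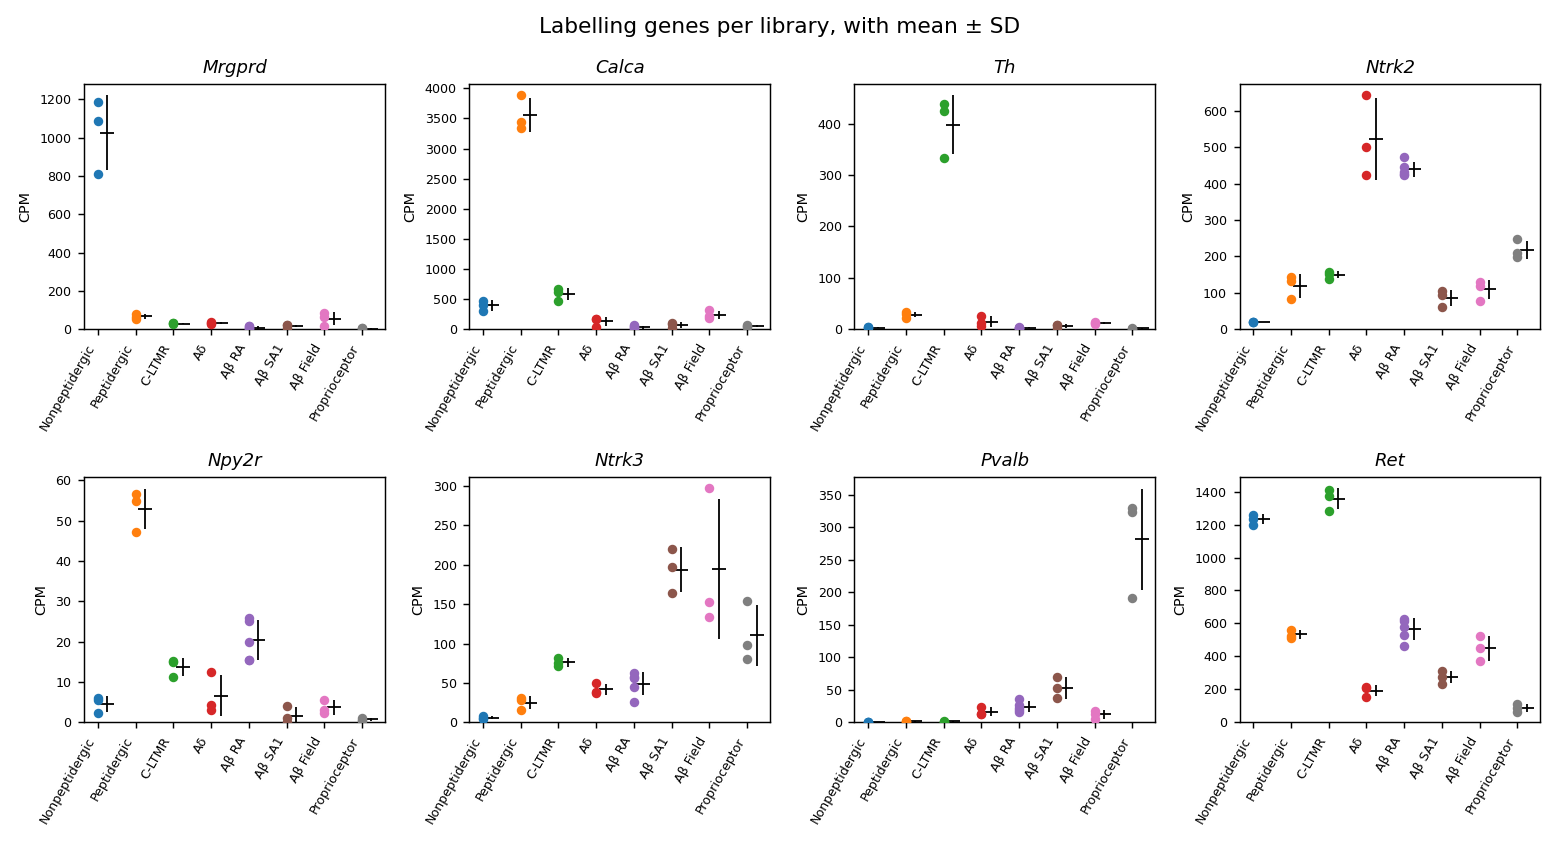
CPM of the 8 labelling genes in each of the 26 libraries by subtype, with a point per library and the mean ± SD beside it. Mrgprd, Calca, Th and Pvalb were each highest in the subtype they label, while Npy2r averaged 52.9 CPM in peptidergic nociceptors against 20.4 CPM in Aβ RA-LTMRs.

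How far apart the subtypes lie was read from all genes. Every one of the 26 libraries had its highest Pearson correlation of log2 CPM with a library of its own subtype, across genes, which are not independent replicates. Average-linkage clustering cut at 8 clusters kept only 5 subtypes whole and apart. The 31 pairs of libraries of one subtype correlated at r = 0.933 to 0.991, and the 294 pairs of different subtypes at r = 0.840 to 0.959. Replicates lay closest in peptidergic nociceptors (r = 0.990 to 0.991) and farthest apart in Aβ SA1-LTMRs (r = 0.933 to 0.951). Of the 1000 genes that varied most, PC1 carried 51.1% of the variance and set the nociceptors and C-LTMRs against the A-fibre subtypes, and PC2 carried 12.4%. 13640 of the 17411 genes differed among the 8 subtypes (edgeR F test). Aβ SA1- and Aβ Field-LTMRs differed in the fewest genes of the 28 pairs, 1545, and nonpeptidergic nociceptors and Aβ RA-LTMRs in the most, 6173. The pair with the fewest changed with the setting: it was Aβ RA- and Aβ SA1-LTMRs on both RPKM scales, for example, and Aδ- and Aβ Field-LTMRs with DESeq2's Wald test. With read-length class as a covariate it was Aδ- and Aβ RA-LTMRs. That class is the range of read lengths in the alignment summary. Reads were 25 to 50 bases long in Aβ RA-LTMR libraries 1 to 3 and all Aβ SA1-LTMR libraries, 15 to 51 in Aδ-LTMR libraries 1 and 2, and 15 to 50 in the others. Only Aβ RA-LTMRs and Aδ-LTMRs hold libraries of more than one class, so for Aβ SA1-LTMRs the class is separated from the subtype only through the Aβ RA-LTMR libraries.

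**Figure D2:**
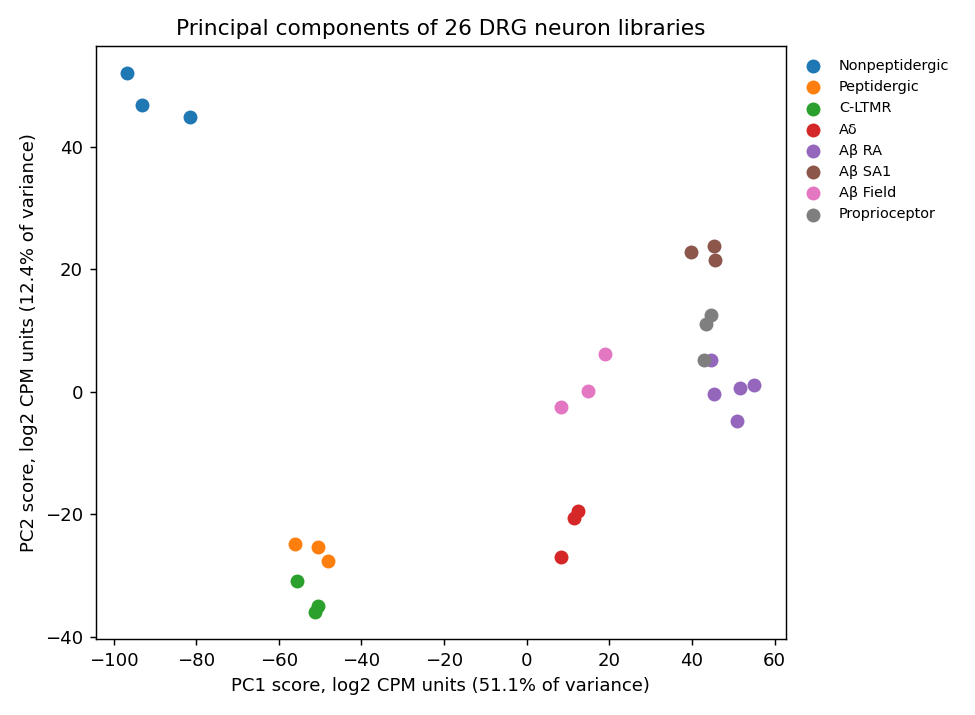
Scores of the 26 libraries on PC1 (51.1% of the variance) and PC2 (12.4%) of log2 CPM over the 1000 most variable genes, coloured by subtype. The 9 nociceptor and C-LTMR libraries lie apart from the 17 A-fibre libraries along PC1.

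RNA of other cells in the sorted fractions was measured as the mean log2 CPM of fixed marker lists, compared over the 8 subtypes by a permutation test of 100000 resamples, adjusted over 11 lists. The satellite glia score ran from 3.49 ± 0.25 in nonpeptidergic nociceptors to 6.64 ± 0.31 in proprioceptors (adjusted p = 5.5e-05, from the smallest p the resamples can give, 1e-05). Apoe, the lipid carrier that satellite glia make, stood at 147 ± 26.1 CPM in nonpeptidergic nociceptors and 1647 ± 553 CPM in proprioceptors. The endothelial score was highest in Aδ-LTMRs, at 1.99 ± 0.43, and lowest in Aβ SA1-LTMRs, at -2.69 ± 0.19 (adjusted p = 0.00135). Aδ-LTMRs also led the fibroblast score, at 2.03 ± 0.19 against -0.82 ± 0.08 in nonpeptidergic nociceptors (adjusted p = 5.5e-05), and the pericyte and smooth muscle score, at 2.18 ± 0.72 against -0.91 ± 0.75 in Aβ Field-LTMRs (adjusted p = 6.6e-04). Myelinating Schwann cell genes ran from 1.77 ± 0.65 in Aβ SA1-LTMRs to 3.32 ± 0.94 in Aδ-LTMRs (adjusted p = 0.0324). Macrophage genes stayed low in every subtype, with a highest mean of -1.15 ± 0.19 in peptidergic nociceptors (adjusted p = 0.0190), as did erythroid genes, at -2.07 ± 0.36 in Aδ-LTMRs (adjusted p = 0.0324). The Hba genes are near-identical copies, so their split is uncertain. Other lists held 1 of the 16 satellite glia genes listed, 1 of 8 pericyte genes, and 0 of 11 endothelial, 12 Schwann cell and 9 fibroblast genes. Stress and immediate early genes were highest in proprioceptors, at 5.10 ± 0.32 (adjusted p = 0.0227), and axon injury genes in peptidergic nociceptors, at 1.4997 ± 0.16 (adjusted p = 0.0227). The axon injury score of Aβ SA1-LTMRs was 1.17 ± 1.57. It ran from -0.51 in library 1 to 2.61 in library 3, the lowest and highest of all 26 libraries. Mitochondrially encoded genes were highest in Aδ-LTMRs, at 10.72 ± 1.22 (adjusted p = 0.0190). This rested on libraries 1 and 2, with mt-Nd5 at 6688 and 8842 CPM against 839 CPM in library 3, and both also stood apart in read length and in mapping rate (61.4% and 74.5%). The sex-linked score joins Xist with Y-linked genes, which move oppositely with sex, so its test over subtypes (adjusted p = 0.199) does not show whether sex differed. Xist stood at 0 CPM in Aβ RA-LTMR libraries 2 and 3 and at 279 CPM in Aδ-LTMR library 1, and the Y-linked Ddx3y at 0.0181 CPM in Aβ RA-LTMR library 1 and 66.4 CPM in library 3. The libraries thus differed in the sex of the mice, which was not a term of the fits.

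**Figure D3:**
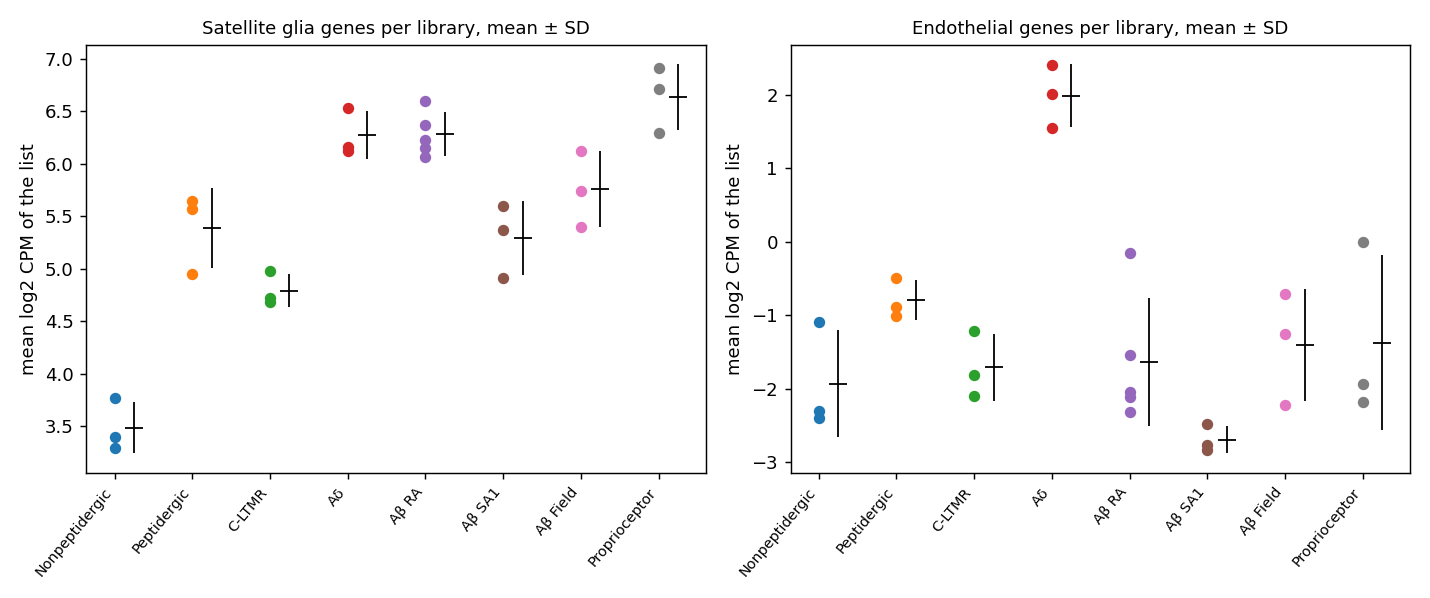
Mean log2 CPM of the satellite glia list (left) and the endothelial list (right) in each of the 26 libraries by subtype, with a point per library and the mean ± SD beside it. Satellite glia genes were lowest in nonpeptidergic nociceptors, at 3.49, and endothelial genes highest in Aδ-LTMRs, at 1.99.

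Genes of a single subtype were sought by setting each subtype against each of the others. Nonpeptidergic nociceptors had 357 such genes, the most of any subtype, and 153 with the satellite glia score as a covariate. Among those at 5 CPM or more, Otoa led (ENSMUSG00000034990, chromosome 7, 121081650 to 121163097). It encodes otoancorin, a protein of the inner ear's gel attachments, and stood at 20.96 ± 2.43 CPM against 0.895 ± 0.310 CPM in peptidergic nociceptors (log2FC 4.55, SE 0.90, adjusted p = 2.7e-04). Lpar5, a receptor for lysophosphatidic acid, followed at 34.5 ± 1.19 CPM (log2FC 4.50, SE 1.05, adjusted p = 0.00163), but missed the threshold with read-length class as a covariate (log2FC 2.04, adjusted p = 0.333). Agtr1a, an angiotensin II receptor, reached 86.5 ± 11.1 CPM (log2FC 4.08, SE 0.51, adjusted p = 6.7e-07). Of 9 marker genes of this class, 7 were enriched. The peptide genes Calcb, at 543 ± 39.1 CPM (log2FC 1.42, SE 0.35, adjusted p = 0.00233), and Nmb, at 559.7 ± 12.47 CPM (log2FC 1.74, SE 0.49, adjusted p = 0.00625), were also highest in these nociceptors.

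Peptidergic nociceptors had 123 genes of their own, and 45 with the glia covariate (193 and 102 at an unadjusted p). Mrgpra4 led (ENSMUSG00000067173, chromosome 7, 47980837 to 47982095) at 7.68 ± 1.03 CPM against 0.351 ± 0.477 CPM in nonpeptidergic nociceptors (log2FC 4.48, SE 1.31, adjusted p = 0.00864). Mrgpra genes lie in a family of close copies, so its share of their reads is uncertain. Avpr1a, a vasopressin receptor (log2FC 3.82, SE 0.88, adjusted p = 0.00272), came next. Insrr, a receptor tyrosine kinase of the insulin receptor family (log2FC 3.46, SE 1.02, adjusted p = 0.0201), and the prokineticin receptor Prokr2, at 91.4 ± 17.2 CPM (log2FC 3.40, SE 0.74, adjusted p = 0.00186), followed. With read-length class as a covariate, Mrgpra4 (log2FC 2.70, adjusted p = 0.403), Insrr (log2FC 2.93, adjusted p = 0.303) and Prokr2 (log2FC 3.03, adjusted p = 0.0661) missed the threshold. Insrr also missed it in 5 of 26 single omissions, up to log2FC 3.41, adjusted p = 0.0884 without C-LTMR library 2. Of 9 peptidergic marker genes, 6 were enriched, among them Kit, the stem cell factor receptor, at 285 ± 48.6 CPM (log2FC 1.95, SE 0.32, adjusted p = 5.9e-05). The peptide gene Adcyap1, at 336 ± 62.6 CPM (log2FC 1.85, SE 0.32, adjusted p = 1.4e-04), was enriched beside Calca.

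C-LTMRs had 157 genes of their own, and 65 with the glia covariate. Bmp15, a growth factor best known from the oocyte (ENSMUSG00000023279, chromosome X, 6314107 to 6320721), stood at 47.0 ± 6.88 CPM against 0.514 ± 0.298 CPM in peptidergic nociceptors (log2FC 6.51, SE 0.74, adjusted p = 4.1e-07). Slc17a8, the vesicular glutamate transporter VGLUT3, reached 167 ± 4.81 CPM against 4.02 ± 0.988 CPM in Aδ-LTMRs (log2FC 5.38, SE 0.75, adjusted p = 8.4e-06). Cacna1i, a T-type calcium channel, stood at 92.3 ± 10.9 CPM (log2FC 5.43, SE 0.78, adjusted p = 1.4e-05). Fam19a4, a secreted peptide of these neurons, stood at 259.5 ± 21.6 CPM (log2FC 2.37, SE 0.30, adjusted p = 8.9e-07). Of 7 tested C-LTMR markers, 5 were enriched, and every one of the 3 C-LTMR libraries lay above every library of the next subtype for each gene named here. 2 of 9 fibroblast genes and 1 of 11 Schwann cell genes were enriched in C-LTMRs as well.

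Aδ-LTMRs had 86 genes of their own, a count that rested on single libraries: 48 without Aδ-LTMR library 1, 42 without library 2, 165 without library 3. There were 14 with the glia covariate, 4 with the endothelial score and 15 with read-length class as a covariate. Adtrp, a fatty acid ester hydrolase that regulates a clotting inhibitor (ENSMUSG00000058022, chromosome 13, 41763148 to 41847684), stood at 15.1 ± 4.62 CPM against 0.197 ± 0.0707 CPM in C-LTMRs (log2FC 6.26, SE 0.88, adjusted p = 3.1e-05). Akr1c14, a steroid dehydrogenase, came next (log2FC 5.20, SE 1.27, adjusted p = 0.00512), with log2FC 3.60 under read-length class. 5 of 11 endothelial marker genes were enriched in these libraries. They included the vascular growth factor receptor Flt1, at 21.6 ± 12.54 CPM (log2FC 4.22, SE 1.18, adjusted p = 0.00952), and the vascular adhesion gene Cdh5, at 6.82 ± 3.15 CPM (log2FC 3.54, SE 1.12, adjusted p = 0.0225). Slco1a4, an anion transporter abundant in brain endothelium, moved with them (log2FC 3.78, SE 1.02, adjusted p = 0.0132). With read-length class as a covariate Flt1 fell to log2FC 2.05, Cdh5 to log2FC 2.80 and Slco1a4 to log2FC 2.55. Flt1 missed the threshold at log2FC 4.02, adjusted p = 0.0551 without peptidergic nociceptor library 1. Cdh5 missed it in 6 of 26 single omissions, up to log2FC 3.16, adjusted p = 0.101 without proprioceptor library 3, and Slco1a4 in 3 of 26 single omissions, up to log2FC 3.49, adjusted p = 0.0798 without Aβ Field-LTMR library 3. With the endothelial score as a covariate Flt1 changed sign to -1.73 and Cdh5 to -0.97, in part by construction, since the score holds both genes. Of 6 Aδ-LTMR markers, 3 were enriched.

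The 3 Aβ subtypes had few genes of their own. Aβ RA-LTMRs had 17, led by Cbln4, a synaptic organiser of the cerebellin family (ENSMUSG00000067578, chromosome 2, 172036233 to 172043466), at 13.9 ± 3.09 CPM against 2.24 ± 1.65 CPM in Aδ-LTMRs (log2FC 2.64, SE 0.63, adjusted p = 0.00398). Calb1, encoding the calcium buffer calbindin, reached 371 ± 113 CPM (log2FC 1.97, SE 0.52, adjusted p = 0.00944). The caveola gene Ptrf (log2FC 1.88, SE 0.56, adjusted p = 0.0195) and the actin bundling gene Fscn1 (log2FC 1.35, SE 0.45, adjusted p = 0.0346) followed. Calb1 missed the threshold at log2FC 1.91, adjusted p = 0.0561 without Aδ-LTMR library 2. Ptrf missed it in 3 of 26 single omissions, up to log2FC 1.72, adjusted p = 0.107 without Aδ-LTMR library 2, and Fscn1 in 5 of 26 single omissions, up to log2FC 1.09, adjusted p = 0.184 without Aδ-LTMR library 2. With read-length class as a covariate edgeR called 0 genes enriched in Aβ RA-LTMRs, against 18 at an unadjusted p and 23 by DESeq2 without the covariate. Under it Cbln4 had log2FC 3.21, adjusted p = 0.0617, Calb1 log2FC 1.78, adjusted p = 0.385, Ptrf log2FC 1.77, adjusted p = 0.450, and Fscn1 log2FC 0.45, adjusted p = 0.820. The count of 17 became 9 with the glia covariate, 3 with the endothelial score, 10 without Aδ-LTMR library 1, 8 without library 2, 9 without Aβ RA-LTMR library 3, 27 without Aβ SA1-LTMR library 2, 9 without proprioceptor library 2 and 11 without library 3. Calb1 was the only enriched gene of 7 Aβ RA-LTMR markers.

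Aβ SA1-LTMRs had 27 genes of their own, 13 with read-length class and 3 with the glia score as a covariate. Nts, the neurotensin gene (ENSMUSG00000019890, chromosome 10, 102481756 to 102490486), led at 36.5 ± 36.6 CPM against 3.39 ± 1.75 CPM in Aδ-LTMRs (log2FC 3.42, SE 0.84, adjusted p = 0.00395), with a spread as large as its mean. Pappa2, a protease that frees insulin-like growth factors, stood at 111 ± 29.1 CPM (log2FC 3.30, SE 0.79, adjusted p = 0.00664), and Vdr, the vitamin D receptor gene, at 9.50 ± 1.29 CPM (log2FC 2.70, SE 0.61, adjusted p = 0.00444). Hrk, a death-promoting gene of the BCL2 family (log2FC 2.85, SE 0.90, adjusted p = 0.0205), missed the threshold in 3 of 26 single omissions, up to log2FC 2.49, adjusted p = 0.0972 without proprioceptor library 3. With read-length class as a covariate Nts (log2FC 3.33, adjusted p = 0.284), Pappa2 (log2FC 0.80, adjusted p = 0.722) and Hrk (log2FC 5.05, adjusted p = 0.205) missed the threshold, and Vdr kept its call. Aβ Field-LTMRs had 24 genes, 13 with read-length class, 10 with the endothelial score, 12 without Aβ Field-LTMR library 1 and 15 without library 3. Htra4, a serine protease gene (ENSMUSG00000037406, chromosome 8, 25024929 to 25038962), stood at 11.2 ± 1.72 CPM against 0.808 ± 0.157 CPM in peptidergic nociceptors (log2FC 3.79, SE 0.74, adjusted p = 8.5e-04). The postsynaptic scaffold gene Dlgap2 (log2FC 2.39, SE 0.67, adjusted p = 0.0203) missed the threshold in 2 of 26 single omissions, up to log2FC 1.98, adjusted p = 0.0954 without Aβ Field-LTMR library 1. Glyat, an amino acid acyltransferase (log2FC 2.18, SE 0.72, adjusted p = 0.0269), missed it in 4 of 26 single omissions, up to log2FC 1.97, adjusted p = 0.114 without peptidergic nociceptor library 1. The nuclear body gene Sp100 (log2FC 1.99, SE 0.66, adjusted p = 0.0423) missed it in 15 of 26 single omissions, up to log2FC 1.88, adjusted p = 0.126 without Aβ Field-LTMR library 3. With read-length class Dlgap2 had log2FC 2.74, adjusted p = 0.157 and Sp100 log2FC 1.99, adjusted p = 0.129.

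Proprioceptors, whose libraries had the highest satellite glia score, had 172 genes of their own, but 18 with that score as a covariate, of which 14 were among the 172. With read-length class the count was 80. Nxph1, a secreted ligand of neurexins (ENSMUSG00000046178, chromosome 6, 8948431 to 9249032), stood at 106 ± 7.85 CPM against 2.75 ± 1.68 CPM in Aβ RA-LTMRs (log2FC 5.26, SE 0.93, adjusted p = 0.00160). Pln, phospholamban, which restrains the calcium pump of the sarcoplasmic reticulum, stood at 90.5 ± 18.9 CPM against 2.77 ± 2.21 CPM in Aβ SA1-LTMRs (log2FC 5.04, SE 0.67, adjusted p = 5.9e-06). Slc38a11, of an amino acid transporter family (log2FC 5.02, SE 0.83, adjusted p = 1.1e-04), missed the threshold with read-length class (log2FC 4.57, adjusted p = 1.000), while the LIM domain gene Lmcd1 did not (log2FC 4.53, SE 0.91, adjusted p = 6.8e-04). Of 9 proprioceptor markers, 6 were enriched, among them the stereocilia scaffold gene Whrn (log2FC 3.60, SE 0.51, adjusted p = 3.2e-06). 4 transcription factor genes were enriched: Etv1, needed for proprioceptor connections, at 456 ± 20.4 CPM (log2FC 1.16, SE 0.26, adjusted p = 7.3e-04; 0.90 on rlog values), Cux2 (log2FC 2.10, SE 0.33, adjusted p = 2.9e-05), Esrrg and Esrrb. Fabp7, a satellite glia gene, was enriched as well, at 979.9 ± 509.8 CPM (log2FC 1.31, SE 0.29, adjusted p = 0.00206), and changed sign to -0.30 with the satellite glia score, in part by construction, since the score holds it.

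Ion channel genes of single subtypes bear on the study's question of what sets each neuron's firing. Of potassium channels, 9 of 38 tested Kv alpha subunit genes, 5 of 11 calcium- or sodium-activated, 3 of 8 inward rectifier, 2 of 12 accessory and 1 of 11 two-pore-domain genes were enriched in 1 subtype. Kcnd3, a subunit of fast inactivating Kv4 channels (ENSMUSG00000040896, chromosome 3, 105452330 to 105674002), stood at 1302 ± 62.7 CPM in C-LTMRs against 188 ± 37.5 CPM in nonpeptidergic nociceptors (log2FC 2.79, SE 0.30, adjusted p = 6.7e-08). C-LTMRs also had the ERG gene Kcnh6, at 123 ± 3.56 CPM (log2FC 1.31, SE 0.21, adjusted p = 3.0e-05), and the Kv4 partner Dpp10, at 699 ± 40.6 CPM (log2FC 1.49, SE 0.29, adjusted p = 2.1e-04). Nonpeptidergic nociceptors had the sodium-activated channel gene Kcnt1, at 318 ± 26.2 CPM (log2FC 1.39, SE 0.23, adjusted p = 3.4e-05). Peptidergic nociceptors had Kcnt2, at 53.5 ± 6.32 CPM (log2FC 2.99, SE 0.44, adjusted p = 1.7e-05), and the silent subunit gene Kcns2 (log2FC 2.86, SE 0.68, adjusted p = 0.00374). In proprioceptors Kcnc1, the Kv3.1 subunit of fast firing neurons, stood at 449 ± 50.8 CPM against 116 ± 22.5 CPM in Aβ SA1-LTMRs (log2FC 1.96, SE 0.22, adjusted p = 7.7e-07). Aβ Field-LTMRs had the silent subunit gene Kcng4 (log2FC 1.49, SE 0.35, adjusted p = 0.00410), which missed the threshold with read-length class as a covariate (log2FC 0.98, adjusted p = 0.145). Kcnt1 (log2FC 0.38, adjusted p = 0.687) and Dpp10 (log2FC 0.31, adjusted p = 0.658) missed it with the glia score.

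**Figure D4:**
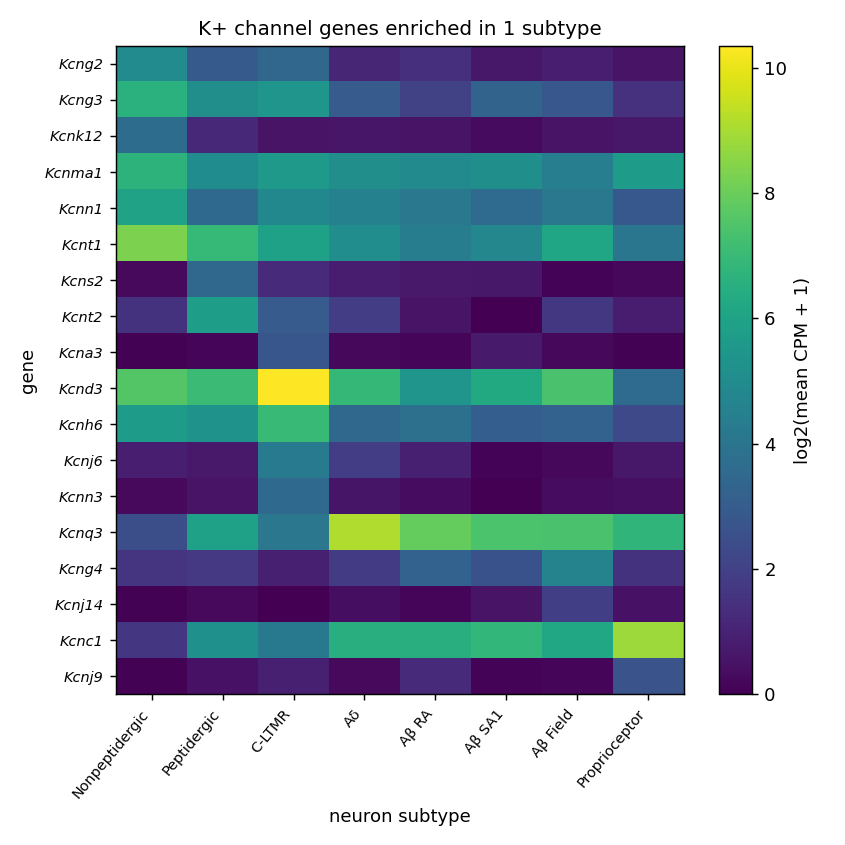
log2(mean CPM + 1) of the K+ channel genes enriched in 1 subtype, genes in lines and the 8 subtypes in columns, means over 3 libraries (5 for Aβ RA-LTMRs). Kcnd3 in C-LTMRs, at 1302 CPM, is the brightest cell of its line, and no gene of these lists is enriched in Aβ RA- or Aβ SA1-LTMRs.

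Among sodium channels, Scn11a, which encodes Nav1.9, stood at 2387 ± 169.9 CPM in nonpeptidergic nociceptors (log2FC 1.41, SE 0.37, adjusted p = 0.00362), and Scn3a at 37.9 ± 1.86 CPM in C-LTMRs (log2FC 1.35, SE 0.33, adjusted p = 0.00328). Of the calcium channels, Cacna1h, the T-type channel Cav3.2, was highest in Aδ-LTMRs, at 231 ± 53.9 CPM (log2FC 1.16, SE 0.30, adjusted p = 0.00498). The TRP channel gene Trpc6 was enriched in nonpeptidergic nociceptors (log2FC 2.05, SE 0.61, adjusted p = 0.00952). Asic3, an acid-sensing channel gene, was highest in Aβ SA1-LTMRs, at 197 ± 45.04 CPM (log2FC 1.31, SE 0.29, adjusted p = 0.00290). The ATP receptor gene P2rx3 was enriched in nonpeptidergic nociceptors, at 447 ± 12.4 CPM (log2FC 1.79, SE 0.35, adjusted p = 2.3e-04). The GABA-A receptor gene Gabra3 was enriched in C-LTMRs (log2FC 1.996, SE 0.39, adjusted p = 1.6e-04), and the kainate receptor gene Grik1 in nonpeptidergic nociceptors, at 437 ± 19.1 CPM (log2FC 1.18, SE 0.29, adjusted p = 0.00240). Trpc6 missed the threshold with no filter (log2FC 1.96, adjusted p = 0.0504), Cacna1h (log2FC 0.91) and Grik1 (log2FC 0.90) on rlog values, and Scn3a on log2(RPKM + 1) (log2FC 0.94). With the glia score Scn11a (log2FC 1.08, adjusted p = 0.464), Asic3 (log2FC 1.11, adjusted p = 0.202) and P2rx3 (log2FC 0.85, adjusted p = 0.554) missed it, and with the endothelial score Scn3a (log2FC 0.40, adjusted p = 0.782) and Cacna1h (log2FC 0.77, adjusted p = 0.490).

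The fast conducting A-fibre types (Aδ, Aβ and proprioceptors, n = 17 libraries) were set against nociceptors and C-LTMRs (n = 9), with every subtype weighted alike. The p-values measure spread between libraries, not between the 5 and 3 subtypes. 2723 genes were higher in A-fibre types and 2246 lower. With the satellite glia score as a covariate there were 1281 and 1147 (1043 and 876 shared), and on rlog values 1440 and 1258. Slc17a7, the vesicular glutamate transporter VGLUT1 (ENSMUSG00000070570, chromosome 7, 45163949 to 45176142), stood at 190 ± 87.4 CPM against 3.92 ± 2.62 CPM (log2FC 5.62, SE 0.19, adjusted p = 1.4e-17). Hapln4, a link protein of perineuronal nets, stood at 178 ± 77.5 CPM against 3.96 ± 2.87 CPM (log2FC 5.52, SE 0.23, adjusted p = 3.2e-16). Ano1, a calcium-activated chloride channel, stood at 33.5 ± 24.4 CPM against 0.584 ± 0.415 CPM (log2FC 5.56, SE 0.26, adjusted p = 1.3e-15). Of genes at 5 CPM or more without overlap between libraries, Myh8, a developmental muscle myosin, rose most, at 11.3 ± 10.1 CPM (log2FC 5.73, SE 0.32, adjusted p = 4.6e-14). Lower were Trpa1, the irritant receptor (chromosome 1, 14872648 to 14918862), at 6.003 ± 6.001 CPM against 140.0 ± 48.6 CPM (log2FC -4.89, SE 0.25, adjusted p = 1.9e-14), and Tmem45b, at 7.34 ± 7.93 CPM against 232 ± 209.9 CPM (log2FC -4.96, SE 0.28, adjusted p = 1.6e-13). The water channel Aqp1 stood at 10.6 ± 10.9 CPM against 202 ± 66.4 CPM (log2FC -4.55, SE 0.26, adjusted p = 1.4e-13). No library of one side overlapped the other in 465 of the higher and 409 of the lower genes. Over all 17411 genes, called or not, this held for 5.81%, where a random grouping of the subtypes gives at most 3.57%. On the authors' RPKM the balance turned, with 770 higher and 1138 lower on log2(RPKM + 1), and 1603 and 2169 on log2(RPKM + 0.1), where the median of all genes was -0.15.

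Of the 42 gene lists fixed in advance, 14 passed camera's test in the A-fibre comparison at the preset correlation, and only 2 of them with an estimated one. Some of the 14 are marker lists of the compared subtypes. Where 2 adjusted p are given, they are camera's at the preset and then the estimated correlation. Every list's counts of higher and lower genes were the same when adjusted over the list alone. Potassium channel genes split. Kcnh5 rose (log2FC 4.76, SE 0.29, adjusted p = 2.4e-13) while Kcnc2 fell (log2FC -3.98, SE 0.16, adjusted p = 8.2e-17), among Kv alpha subunits with 15 of 38 members higher and 11 lower (camera adjusted p = 0.615). Calcium- and sodium-activated channels had 1 of 11 members higher and 5 lower and passed (camera adjusted p = 0.00245 and 0.0449). Kcnt2 led them (log2FC -4.18, SE 0.25, adjusted p = 1.6e-13). Kcnip2, a Kv4 partner, fell (log2FC -2.96, SE 0.17, adjusted p = 5.3e-14) among Kv accessory genes, with 2 of 12 members higher and 4 lower (camera adjusted p = 0.482). The two-pore gene Kcnk1 rose (log2FC 3.41, SE 0.16, adjusted p = 1.7e-15) in a list with 1 of 11 members higher and 5 lower (median log2FC 0.04, mean -0.47, camera downward, adjusted p = 0.864). Inward rectifiers had 3 of 8 members higher and 1 lower (camera adjusted p = 0.857). Scn10a, which encodes Nav1.8 of nociceptors, fell from 1443 ± 745 CPM to 77.1 ± 69.4 CPM (log2FC -4.31, SE 0.26, adjusted p = 3.7e-13). Scn1a rose to 503 ± 125 CPM (log2FC 3.93, SE 0.25, adjusted p = 1.0e-12). Sodium channels had 5 of 17 members higher and 9 lower (camera adjusted p = 0.482). Cacna1e (log2FC -4.23, SE 0.31, adjusted p = 2.2e-11) led a calcium channel list with 2 of 16 members higher and 7 lower (camera adjusted p = 0.197). Hcn2 rose (log2FC 2.10, SE 0.13, adjusted p = 2.8e-13) in an HCN list with 2 of 4 members higher and 1 lower (camera adjusted p = 0.617).

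TRP channels were lower in A-fibre types, with 1 of 17 members higher and 10 lower (camera adjusted p = 0.00135 and 0.0678). Beside Trpa1, the capsaicin receptor gene Trpv1 fell from 94.3 ± 65.2 CPM to 4.30 ± 3.66 CPM (log2FC -4.14, SE 0.31, adjusted p = 4.7e-11). Asic3 rose (log2FC 3.11, SE 0.20, adjusted p = 6.9e-13) in a list of mechanotransduction and acid-sensing channels with 3 of 13 members higher and 3 lower (median log2FC -0.22, mean 0.18, camera downward, adjusted p = 0.961). Chloride channels had 4 of 13 members higher and 2 lower (median log2FC -0.27, mean 0.35, camera downward, adjusted p = 0.878), with Ano3 falling as Ano1 rose (log2FC -1.999, SE 0.08, adjusted p = 1.1e-16). P2rx6 rose (log2FC 4.35, SE 0.17, adjusted p = 1.1e-16) and P2rx3 fell (log2FC -3.57, SE 0.17, adjusted p = 4.1e-15) among ATP and acetylcholine gated channels, with 3 of 18 members higher and 7 lower (camera adjusted p = 0.615). GABA-A and glycine receptors had 8 of 18 members higher and 3 lower, with Gabrg1 at 56.4 ± 35.2 CPM against 1.85 ± 1.28 CPM (log2FC 4.999, SE 0.25, adjusted p = 5.3e-15). That list passed (camera adjusted p = 0.0123 and 0.348), but not with read-length class as a covariate (adjusted p = 0.0622). Grik1 fell (log2FC -3.26, SE 0.15, adjusted p = 8.4e-16) among ionotropic glutamate receptors, with 7 of 16 members higher and 5 lower (camera adjusted p = 0.667). The serotonin receptor gene Htr7 rose to 40.2 ± 17.5 CPM (log2FC 5.22, SE 0.24, adjusted p = 1.1e-15) in a list of modulatory receptors with 10 of 41 members higher and 16 lower (camera adjusted p = 0.615).

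Mas-related receptors were lower, with 0 of 11 members higher and 9 lower (camera adjusted p = 1.7e-05 and 0.0678). The itch receptor Mrgpra3 stood at 2.01 ± 2.09 CPM in A-fibre types against 64.9 ± 75.8 CPM (log2FC -3.96, SE 0.37, adjusted p = 2.4e-09), with reads that close copies may share. Neuropeptide genes had 2 of 18 members higher and 12 lower (camera adjusted p = 0.00135 and 0.124). Tac1, which encodes substance P (log2FC -3.34, SE 0.21, adjusted p = 5.1e-13) and Calca (log2FC -3.48, SE 0.29, adjusted p = 3.2e-10) fell. Gfra3, the artemin receptor, fell (log2FC -3.54, SE 0.22, adjusted p = 6.4e-13) among receptors of neurotrophic factors, with 3 of 15 members higher and 8 lower (camera adjusted p = 0.502). Nefh, the heavy neurofilament of large axons, rose from 287 ± 214 CPM to 3041 ± 905 CPM (log2FC 3.64, SE 0.13, adjusted p = 3.0e-17). The neurofilament list had 5 of 12 members higher and 2 lower (camera adjusted p = 0.0423 and 0.360). It did not pass with read-length class as a covariate (adjusted p = 0.0763) or without Aβ SA1-LTMR library 3 (adjusted p = 0.0523). Transcription factors went both ways, with 13 of 36 members higher and 10 lower (camera adjusted p = 0.502), Esrrg (log2FC 5.29, SE 0.23, adjusted p = 3.7e-16) up and Ldb2 down (log2FC -4.39, SE 0.14, adjusted p = 2.9e-18). Vesicular transporters had 2 of 9 members higher and 2 lower (median log2FC -0.22, mean 0.27, camera upward, adjusted p = 0.864). Nuclear genes of oxidative phosphorylation were higher, with 11 of 27 members higher and 0 lower (camera adjusted p = 1.1e-07 and 0.360). Cox5a was among them (log2FC 1.64, SE 0.23, adjusted p = 1.7e-06). Ribosomal protein genes had 0 of 28 members higher and 3 lower (camera adjusted p = 0.158), which passed without Aδ-LTMR library 3 (adjusted p = 0.0375), and processed pseudogenes may share their reads. Adhesion and guidance genes had 34 of 69 members higher and 7 lower (camera adjusted p = 1.5e-04 and 0.425). Slit2 led at 100.5 ± 76.0 CPM against 2.93 ± 2.13 CPM (log2FC 5.16, SE 0.21, adjusted p = 1.2e-16).

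The direction of the subtypes' own markers follows in part from how the sides were drawn. Lists also share genes, such as 8 of 9 nonpeptidergic markers. Nonpeptidergic markers had 0 of 9 members higher and 9 lower (camera adjusted p = 5.1e-07 and 0.0678). Peptidergic markers had 0 of 9 higher and 8 lower (camera adjusted p = 2.1e-05 and 0.0843). C-LTMR markers had 0 of 7 higher and 5 lower (camera adjusted p = 0.00885 and 0.210). Aδ-LTMR markers had 4 of 6 higher and 0 lower (camera adjusted p = 0.00135 and 0.0449). Proprioceptor markers had 6 of 9 higher and 0 lower (camera adjusted p = 6.3e-05 and 0.0678). Aβ RA-LTMR markers had 3 of 7 members higher and 3 lower (camera adjusted p = 0.857), and the 8 labelling genes 3 higher and 5 lower (camera adjusted p = 0.615). Satellite glia genes were higher in A-fibre types too, with 13 of 16 members higher and 0 lower (camera adjusted p = 5.1e-07 and 0.166). Among them were S100b, at 711 ± 175 CPM against 70.6 ± 72.8 CPM (log2FC 4.03, SE 0.17, adjusted p = 2.6e-16), which large sensory neurons also make. The gap junction gene Gja1 (log2FC 2.38, SE 0.25, adjusted p = 6.8e-09) and the glutamate transporter gene Slc1a3 (log2FC 1.96, SE 0.17, adjusted p = 4.3e-10) were others. The lists of other cell types did not pass. Schwann cells had 4 higher and 1 lower of 11 (camera adjusted p = 0.698), and fibroblasts 5 and 2 of 9 (camera adjusted p = 0.502). Endothelial cells had 1 and 1 of 11 (camera adjusted p = 0.584), and macrophages 1 and 2 of 6 (camera adjusted p = 0.615). Pericyte genes had 1 of 7 members higher and 1 lower (median log2FC -0.16, mean 0.04, camera upward, adjusted p = 0.958), and erythroid genes 2 of 4 members higher and 0 lower (camera adjusted p = 0.615). Stress genes had 3 of 19 members higher and 0 lower (camera adjusted p = 0.603), and axon injury genes 1 of 13 members higher and 4 lower (median log2FC 0.23, mean 0.27, camera downward, adjusted p = 0.615). Sex-linked genes had 0 of 5 members higher and 0 lower (median log2FC 0.26, mean -0.10, camera downward, adjusted p = 0.864), and mitochondrially encoded genes 0 of 7 members higher and 0 lower (camera adjusted p = 0.482).

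The 2 nociceptor classes were set against each other, n = 3 libraries each. Peptidergic nociceptors were higher in 2666 genes and lower in 1906, and in 1022 and 554 with the satellite glia score as a covariate (906 and 443 shared). Chrnb4, a nicotinic receptor subunit (ENSMUSG00000035200, chromosome 9, 55028154 to 55048779), stood at 65.2 ± 3.79 CPM in them against 0.518 ± 0.136 CPM in nonpeptidergic nociceptors (log2FC 6.95, SE 0.99, adjusted p = 6.8e-06). Slc5a7, the choline transporter of cholinergic neurons, stood at 23.8 ± 0.936 CPM against 0.198 ± 0.0455 CPM (log2FC 6.88, SE 0.91, adjusted p = 1.5e-06). Casr, the calcium-sensing receptor (log2FC 7.59, SE 1.02, adjusted p = 2.0e-06), rose too. Fam26d had 894 counts in the peptidergic and 2 in the nonpeptidergic libraries, a ratio of 415 (95% interval 114 to 3429, for counting error only). Higher in nonpeptidergic nociceptors were Ms4a3, at 34.3 ± 4.59 CPM against 0.572 ± 0.284 CPM (log2FC -5.91, SE 0.83, adjusted p = 3.8e-06), and the stress gene Nupr1 (log2FC -5.92, SE 1.01, adjusted p = 6.6e-05). Libraries of the higher and lower side did not overlap in 2634 and 1886 of these genes. Over all 17411 genes, called or not, 67.8% did not overlap, where chance gives 10% for 3 against 3. On the authors' rlog values the balance was 2310 higher and 1012 lower.

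Of 15 neurotrophic factor receptors, 7 were higher in peptidergic nociceptors and 2 lower (7 and 2 adjusted over the list alone). Ngfr, the low-affinity nerve growth factor receptor, stood at 890.2 ± 32.5 CPM against 23.7 ± 4.25 CPM (log2FC 5.23, SE 0.26, adjusted p = 3.6e-13). Gfra2, the neurturin receptor, stood at 45.4 ± 16.98 CPM against 869 ± 21.6 CPM (log2FC -4.26, SE 0.46, adjusted p = 5.5e-08). Kv alpha subunits had 17 higher and 5 lower (17 and 5 adjusted over the list alone), led by Kcng1 (log2FC 6.10, SE 1.13, adjusted p = 1.4e-04) and Kcns2 (log2FC 5.77, SE 0.80, adjusted p = 2.9e-06). Sodium channels had 8 higher and 1 lower (9 and 1 adjusted over the list alone), and TRP channels 4 higher and 3 lower (4 and 3 adjusted over the list alone). The cold receptor Trpm8 stood at 50.1 ± 7.19 CPM against 1.65 ± 0.152 CPM (log2FC 4.93, SE 0.72, adjusted p = 8.6e-06). Neuropeptide genes had 7 higher and 3 lower (7 and 4 adjusted over the list alone), among them Adcyap1 (log2FC 5.81, SE 0.39, adjusted p = 1.5e-11). Ribosomal protein genes were lower in peptidergic nociceptors, 0 higher and 21 lower (0 and 21 adjusted over the list alone) of 28. Rplp1 (log2FC -3.16, SE 0.67, adjusted p = 7.2e-04) was among them, at a level that pseudogene copies leave uncertain. Oxidative phosphorylation genes had 0 higher and 13 lower (0 and 14 adjusted over the list alone) of 27, among them Cox5b (log2FC -2.399). Satellite glia genes moved the other way, 14 higher and 0 lower (14 and 0 adjusted over the list alone) of 16, with S100b at 165 ± 28.3 CPM against 14.9 ± 7.72 CPM (log2FC 3.47, SE 0.30, adjusted p = 1.1e-09).

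Aδ-LTMRs and Aβ RA-LTMRs are both rapidly adapting touch receptors of different conduction velocity, compared here with n = 3 and n = 5 libraries. 1441 genes were higher in Aδ-LTMRs and 473 lower. Adtrp led the genes at 5 CPM or more, 15.1 ± 4.62 CPM against 0.0333 ± 0.0543 CPM (log2FC 8.87, SE 0.85, adjusted p = 1.4e-07), and Nxpe2 stood at 50.7 ± 20.003 CPM against 0.832 ± 0.188 CPM (log2FC 5.91, SE 0.43, adjusted p = 7.4e-10). Kcnc2, a Kv3 potassium channel subunit, stood at 37.5 ± 10.5 CPM against 3.87 ± 0.968 CPM (log2FC 3.27, SE 0.27, adjusted p = 5.6e-09). Rgs5, listed as a pericyte gene, stood at 311 ± 179 CPM against 1.24 ± 0.905 CPM (log2FC 8.05, SE 1.28, adjusted p = 1.6e-04). It was higher still in C-LTMR libraries, at 681 to 1750 CPM, where Flt1 lay between 0.0780 and 0.397 CPM, so Rgs5 alone does not mark vessel cells here. The endothelial gene Cdh5 stood at 6.82 ± 3.15 CPM (log2FC 6.42, SE 1.07, adjusted p = 1.4e-04), and Cd93, another endothelial gene, at 13.8 ± 5.79 CPM (log2FC 5.98, SE 1.03, adjusted p = 2.0e-04). Lower in Aδ-LTMRs were Me3, a mitochondrial malic enzyme, at 3.21 ± 1.43 CPM against 21.6 ± 0.982 CPM (log2FC -2.74, SE 0.36, adjusted p = 8.8e-06), and the secreted gene Nell2 (log2FC -2.57, SE 0.44, adjusted p = 1.7e-04). With read-length class as a covariate Aδ-LTMR library 3 alone stands for its subtype, so only effect sizes are given. Without Aδ-LTMR library 1 the higher count was 901, without library 2 the lower count was 306, and without library 3 there were 1830 higher and 1011 lower. With the endothelial score as a covariate the split was 204 and 137, of which 158 and 89 were among the 1441 and 473, and with no minimum fold 2241 and 1274. Nxpe2, Kcnc2, Me3, Fam19a4 and Syndig1l kept their calls with the endothelial score. Adtrp (log2FC 5.71, adjusted p = 0.0573) and Prom1 (log2FC 3.26, adjusted p = 0.394) did not. With read-length class Rgs5 had log2FC 6.26, Cdh5 log2FC 4.81, Cd93 log2FC 4.20 and Nell2 log2FC -2.35.

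Further genes higher in Aδ-LTMRs were Prom1 (log2FC 5.66, SE 0.94, adjusted p = 1.3e-04) and Akr1c14 (log2FC 6.90, and 5.66 with the read-length covariate). Further genes lower in them were Syndig1l (log2FC -2.38, SE 0.43, adjusted p = 3.0e-04) and the lectin gene Chodl (log2FC -3.22, covariate log2FC -1.02). The pseudogene Rps2-ps13, whose reads its parent gene may share, was lower too (log2FC -3.68, covariate log2FC -3.71). Chodl missed the threshold in 3 of 26 single omissions, up to log2FC -3.05, adjusted p = 0.0746 without Aδ-LTMR library 2, and Rps2-ps13 in 4 of 26 single omissions, up to log2FC -3.50, adjusted p = 0.144 without Aδ-LTMR library 1. Neuropeptide genes had 10 higher and 1 lower (11 and 1 adjusted over the list alone), with Fam19a4 (log2FC 2.93, SE 0.27, adjusted p = 4.4e-08). Sodium channels had 7 higher and 0 lower (7 and 0 adjusted over the list alone), Kv alpha subunits 11 higher and 4 lower (12 and 5 adjusted over the list alone), and modulatory receptors 9 higher and 6 lower (10 and 7 adjusted over the list alone). Endothelial genes had 9 higher and 0 lower of 11, pericyte genes 4 and 0 of 7, and fibroblast genes 4 and 0 of 9. These were the same over the list alone. Axon injury genes had 6 higher and 0 lower (7 and 0 adjusted over the list alone) of 13. In 988 of the higher and 405 of the lower genes no library overlapped. Over all 17411 genes this held for 17.6%, where chance gives 3.57% for 3 against 5.

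Aβ SA1- and Aβ Field-LTMRs carried the same reporter alleles and were labelled by tamoxifen at different days and doses, 3 mg on 1 embryonic day and 2 mg a day over postnatal days 13 to 14 or 14 to 15, with n = 3 libraries each. 559 genes were higher in Aβ SA1-LTMRs and 986 lower. Runx3, a transcription factor gene of early TrkC neurons (ENSMUSG00000070691, chromosome 4, 135120652 to 135177990), stood at 61.9 ± 16.7 CPM against 1.81 ± 1.36 CPM (log2FC 5.28, SE 0.74, adjusted p = 5.1e-05). Slit2, a guidance gene, stood at 164 ± 57.9 CPM against 13.3 ± 4.13 CPM (log2FC 3.64, SE 0.34, adjusted p = 3.4e-07). The acid-sensing channel gene Asic3 (log2FC 1.90, SE 0.34, adjusted p = 6.3e-04) was higher too. Pappa2 stood at 111 ± 29.1 CPM against 1.63 ± 1.67 CPM (log2FC 6.42, SE 1.16, adjusted p = 9.2e-04). The Kv1 channel gene Kcna4 was lower (log2FC -3.11, SE 0.51, adjusted p = 2.3e-04). Glyat (log2FC -4.61, SE 0.81, adjusted p = 5.3e-04), Htra4 (log2FC -4.01, SE 0.74, adjusted p = 8.5e-04) and the transporter gene Slc4a11 (log2FC -3.32, SE 0.38, adjusted p = 3.1e-06) were lower as well. Libraries did not overlap in 464 of the higher and 831 of the lower genes, and in 21.5% of all 17411 genes, where chance gives 10%. All Aβ SA1-LTMR libraries share a read-length class that no Aβ Field-LTMR library has. With the class as a covariate 708 genes were higher and 937 lower, and these held 297 of the 559 and 458 of the 986. Under it Pappa2 (log2FC 3.26, adjusted p = 0.0875) and Hrk (log2FC 8.54, adjusted p = 0.0530 from log2FC 6.34) missed the threshold. So did A3galt2 (log2FC -2.08, adjusted p = 0.0701 from log2FC -4.26), Slco2a1 (log2FC -3.55, adjusted p = 0.0563 from log2FC -3.07) and Fam26d (log2FC -3.66, adjusted p = 0.0986 from log2FC -2.90). Slco2a1 also missed it at log2FC -2.38, adjusted p = 0.0706 without Aβ Field-LTMR library 1, and Fam26d in 21 of 26 single omissions, up to log2FC -2.37, adjusted p = 0.154 without Aβ Field-LTMR library 3.

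mt-Nd6, the mitochondrial gene on the strand opposite to its neighbours, fell to 54.3 ± 2.48 CPM in Aβ SA1-LTMRs against 623 ± 788 CPM (log2FC -3.52, SE 0.89, adjusted p = 0.0126). This call rested on 1 library (log2FC -1.64, adjusted p = 0.174 without Aβ Field-LTMR library 2). The strand setting of the counting is not given in the sources used here, so reads of mt-Nd6 and its antisense neighbours cannot be told apart. Of 38 Kv alpha subunits, 1 was higher in Aβ SA1-LTMRs and 8 lower (2 and 8 adjusted over the list alone). Of 41 modulatory receptors, 1 was higher and 10 lower (1 and 11 adjusted over the list alone), and of 18 neuropeptide genes, 2 higher and 7 lower (3 and 8 adjusted over the list alone). Nts rose on average (log2FC 4.004, SE 0.88, adjusted p = 0.00373), but Aβ SA1-LTMR library 1, at 0.947 CPM, lay below every Aβ Field-LTMR library (1.55 to 2.84 CPM). Read-length class as a covariate left Nts just short of the threshold (log2FC 4.06, adjusted p = 0.0503). Transcription factors had 5 higher and 7 lower (5 and 8 adjusted over the list alone), and endothelial genes 0 higher and 2 lower (0 and 4 adjusted over the list alone). The balance of calls turned with the unit and the samples: 418 higher and 193 lower on log2(RPKM + 1), 808 and 539 on log2(RPKM + 0.1), and 199 and 139 when only the 6 libraries of these subtypes were fitted.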

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

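The read-length tests, the omission of list members, the Schwann cell test of purity, the neurofilament control, the control that left out any 3 subtypes and the regrouping of whole subtypes were chosen after the results were seen; the other tests of this part were set beforehand. Aβ RA-LTMRs, the only subtype with 5 libraries, were searched for a single library far from the other 4, in 49 values, and 7 were found. Th stood at 4.99 CPM in Aβ RA-LTMR library 1 against 2.47 to 2.93, Chodl at 15.3 CPM in library 3 against 0.933 to 4.34, and Cd93 at 0.812 CPM in library 5 against 0 to 0.133. Akr1c14 stood at 0.167 CPM in library 2 against 0 to 0.0444, and Rasgrp3 at 0.222 CPM in library 4 against 0 to 0.0628. The sex-linked score, which holds Xist and Y-linked genes, was -2.14 in library 1 against 3.11 to 3.67, and the mapping rate was 93.7% in library 5 against 96.8% to 97.7%. The 4 Y-linked genes lay at 0 to 0.0181 CPM in library 1, with Xist at 90.5 CPM, so its mice were female by these genes. Chance picks out about 1 in 20 groups by this rule, and no explanation of the other 6 was tested.

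Endothelial genes were highest in Aδ-LTMR libraries, with Flt1 at 21.6 CPM, Pecam1 at 8.06 CPM and Cdh5 at 6.82 CPM, although neurons were sorted by their reporter. Of the pericyte list, Rgs5 was higher in C-LTMR (681 to 1750 CPM) than in Aδ-LTMR libraries (162 to 510 CPM). If RNA of vessel cells came along in the sort, the genes enriched in Aδ-LTMRs would follow the endothelial score in the other 23 libraries, and outside the endothelial list 8.64% did (7 of 81, r above 0.5, SE 3.12 for independent genes), against 3.20% of other genes. With the 5 list members, each set against a score without itself, it was 11.6% (10). The 8.64% lies under 10% by less than 2 SE. The test cannot decide, since the score lay near the floor in those 23 libraries (subtype means -2.69 to -0.79). Vessel RNA remains a candidate source of some of these genes, not told apart from Aδ neurons' own expression. The read-length class of Aδ-LTMR libraries 1 and 2 stays open as the cause. The median log2 difference from Aβ RA-LTMRs of 9 endothelial genes, picked as higher there, was 4.20 without and 2.81 with it as a covariate. Aδ-LTMR library 3 alone then stands for its subtype. The median SE rose from 0.85 to 1.29, and the values ran from 1.11 to 5.96.

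Satellite glia genes were higher in A-fibre libraries, and glial RNA carried along with large neurons may raise them. With the glia score as a covariate 38.3% of the 2723 genes higher in A-fibre types passed again (1043), which met the prediction for glial RNA. A neurofilament score, which is neuronal, left 42.0%, so the test does not separate glia from fibre class. The covariate moved the median log2FC from 1.83 to 1.64 and the median SE from 0.26 to 0.72. Within subtypes 9.93% of these genes (269 of 2710 outside the glia list, SE 0.57) followed the glia score, against 2.81% of other genes, and 10.3% (280) with the 13 list members. The 9.93% lies under the bound of 10% by less than 2 SE, which leaves glial RNA and neuronal expression unresolved. A general loss of purity stays open in part. The glia score rose by 1.49 (SE 0.12) and the Schwann cell score by 0.37 (SE 0.21), 1.12 apart (SE 0.24), where an equal share of every other cell would raise both alike. The bound set for this test was not met: the Schwann cell difference lay 0.37 (SE 0.22) below 50% of the glia difference, under 2 SE. The fibroblast score rose by 0.60 (SE 0.13). The macrophage score, -0.73 (SE 0.19), was looked at first and set aside because its genes lie near the floor.

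Aβ RA-, SA1- and Field-LTMRs had 17, 27 and 24 genes of their own, against 86 to 357 in other subtypes. Wider spread between replicates is argued against: by the fold alone, with no p-value, they had 23, 26 and 36 genes, at most 22.6% of the median of 159 in the other subtypes. Whether expression shared with the neighbouring LTMRs accounts for it stays open. Leaving the other A-fibre LTMRs out of the comparison raised the counts at least 8.29 times, to 214, 226 and 199, but leaving out comparisons raises a count by construction. Leaving out any 3 subtypes (35 choices) gave medians of 79, 81 and 78. The highest counts were 366, 382 and 205, each without proprioceptors and 2 other A-fibre LTMRs, so no special part of the LTMRs among A-fibre types was shown. Read-length class is argued against as the whole cause. Aβ Field-LTMR libraries are all of the common class. With the class as a covariate the counts by the fold alone, again at 5 CPM or more, were 18, 36 and 51. These are at most 32.5% of the median of 157 in the other subtypes. With p-values the counts were 0, 13 and 13.

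Random groupings of the 26 libraries, 100 with the real one, mix the subtypes, which widens the spread within groups and lowers a count beforehand. They exclude only that libraries were assigned to subtypes at random. The 13640 genes that differ among subtypes compared with at most 465 in the other groupings, and 1 of 100 was as large, the real one. For each subtype's own genes (357, 123, 157, 86, 17, 27, 24 and 172) the highest other count was 0. The A-fibre comparison was set against all 56 groupings of the 8 subtypes into 5 and 3. For 2723 higher genes 1 grouping, the real one, was as large (highest other 2417), so a random grouping is excluded for it. For 2246 lower 2 of 56 were, under 5%, but another grouping gave more (2748), so the lower count was not the largest. For the 14 gene lists 12 groupings were as large, with a highest other of 23, so chance is not excluded for that count. For Aδ- against Aβ RA-LTMRs, 1 of 56 splits, the real one, was as large, with 1441 higher against at most 684, and 473 lower against at most 458. For the pairs of 3 libraries each, 10 splits are too few: peptidergic against nonpeptidergic nociceptors gave 2666 and 1906 with a highest other of 0, and Aβ SA1- against Aβ Field-LTMRs 559 and 986 with a highest other of 89.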

How the results depend on the processing

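The alternatives chosen after seeing the data are named above, with the simulations. Of values of named genes under alternatives other than single omissions, 4566 kept their direction and side of the threshold, 414 lost the call and 9 changed sign; of counts, 276 stayed within 1.5 times and 71 did not. The cause was not tested unless stated. DESeq2's size factors, its Wald test, no filter and the exonic share moved no count of genes by more than 1.5 times. Nor did omitting Aβ RA-LTMR libraries 4 and 5, libraries under 60% exonic reads, or mt-Rnr1, mt-Rnr2 and Gm26924.

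With no minimum fold, which can only add genes, nonpeptidergic nociceptors had 805 of their own, peptidergic 185, C-LTMRs 242, Aβ RA-LTMRs 29, Aβ SA1-LTMRs 49, Aβ Field-LTMRs 53 and proprioceptors 312. A-fibre types were then higher in 4945 and lower in 4891, peptidergic nociceptors lower in 3219, Aδ-LTMRs higher than Aβ RA-LTMRs in 2241 and lower in 1274, and Aβ SA1-LTMRs higher than Aβ Field-LTMRs in 889. On rlog values Aβ Field-LTMRs had 48, A-fibre types 1440 higher and 1258 lower, peptidergic nociceptors 1012 lower, and Aβ SA1-LTMRs 371 higher. On log2(RPKM + 1) the pair with the fewest had 472 and with the most 3676, Aδ-LTMRs 45, Aβ RA-LTMRs 9 and Aβ Field-LTMRs 13. A-fibre types had 770 and 1138, peptidergic nociceptors 1478 and 1264, Aδ-LTMRs 500 and 212, and Aβ SA1-LTMRs 193 lower. On log2(RPKM + 0.1) peptidergic nociceptors had 222, C-LTMRs 242, Aδ-LTMRs 131, Aβ RA-LTMRs 31 and Aβ SA1-LTMRs 46, A-fibre types 1603 higher, and Aβ SA1-LTMRs 539 lower. Thinned to the smallest library, Aβ SA1-LTMRs were lower in 641, which shows what depth limits.

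With the satellite glia score as a covariate the fewest was 466, 2 labelling genes passed in place of 4, and own genes were 153 in nonpeptidergic nociceptors, 45 in peptidergic, 65 in C-LTMRs, 14 in Aδ-, 9 in Aβ RA-, 3 in Aβ SA1-LTMRs and 18 in proprioceptors. A-fibre types had 1281 and 1147, and peptidergic nociceptors 1022 and 554. Kcnj4 changed sign to -0.57, Trpv4 to -0.37 and Fabp7, part of the score, to -0.30, and the satellite glia list changed direction by construction (adjusted p = 0.919). With read-length class the fewest was 343, own genes 15 in Aδ-LTMRs, 0 in Aβ RA-LTMRs (edgeR; 18 at unadjusted p, 23 by DESeq2 without the covariate), 13 in Aβ SA1-, 13 in Aβ Field-LTMRs and 80 in proprioceptors, and Aδ- against Aβ RA-LTMRs 259 and 84. With the endothelial score the fewest was 341, own genes 76 in peptidergic nociceptors, 66 in C-LTMRs, 4 in Aδ-, 3 in Aβ RA-, 16 in Aβ SA1-, 10 in Aβ Field-LTMRs and 91 in proprioceptors, and Aδ- against Aβ RA-LTMRs 204 and 137. Under it Flt1 changed sign to -1.73, Emcn to -1.97, Cdh5 to -0.97, Pecam1 to -0.70, Tek to -0.68 and Gabrq to -0.17, where all but Gabrq are part of the score. Fitting only the 6 libraries of the pair gave 199 and 139 for Aβ SA1- against Aβ Field-LTMRs. This fit had fewer samples for the spread and no subtypes of smaller spread.

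Single omissions kept 532 counts within 1.5 times and moved 14. Own genes of Aδ-LTMRs ran from 42 (without Aδ-LTMR library 2) to 165 (without library 3), with 48 without library 1. Those of Aβ RA-LTMRs ran from 8 (without Aδ-LTMR library 2) to 27 (without Aβ SA1-LTMR library 2), with 10 without Aδ-LTMR library 1, 9 without Aβ RA-LTMR library 3, and 9 and 11 without proprioceptor libraries 2 and 3. Those of Aβ Field-LTMRs ran from 12 (without Aβ Field-LTMR library 1) to 33, with 15 without library 3. Aδ- against Aβ RA-LTMRs ran from 901 (without Aδ-LTMR library 1) to 1830 higher, and from 306 (without library 2) to 1011 lower (without library 3). Of the gene lists, neurofilaments (adjusted p 0.0423) missed the threshold with the replicate block (0.0553), rlog (0.0523), log2(RPKM + 1) (0.0543), log2(RPKM + 0.1) (0.0664), thinned counts (0.0611), read-length class (0.0763), no libraries under 60% exonic reads (0.0502) and no Aβ SA1-LTMR library 3 (0.0523). GABA-A receptors missed it on log2(RPKM + 1) (0.0740) and with read-length class (0.0622). Endothelial genes passed on log2(RPKM + 1) (0.0201), and ribosomal genes without peptidergic nociceptors (0.00746), proprioceptors (0.0492) or Aδ-LTMR library 3 (0.0375).

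Replicate numbers are shared by the subtypes but do not pair the libraries: the deviations of 84 pairs with the same number had a median correlation of 0.0015, 4 were over 0.1, and 9 of 24 libraries correlated best with their own number. The pair with the fewest genes was Aβ RA- and Aβ SA1-LTMRs with the replicate block, RPKM, the glia score or exonic share, and without Aβ RA-LTMR libraries 4 and 5, Aβ RA-LTMR library 5 or Aβ SA1-LTMR library 1. It was Aδ- and Aβ RA-LTMRs with read-length class, the endothelial score and without Aδ-LTMR library 1. It was Aδ- and Aβ Field-LTMRs with the Wald test and without Aδ-LTMR library 2 or Aβ Field-LTMR library 1 or 3, peptidergic nociceptors and C-LTMRs without C-LTMR library 2, and Aβ RA-LTMRs and proprioceptors without proprioceptor library 2 or 3. The replicate block changed the counts to 1519 for the fewest, 6263 for the most, 391 for nonpeptidergic nociceptors and 13 gene lists, none by more than 1.5 times.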

Other observations

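The test of summed levels was chosen after the result was seen, and the other before. Of 31 tested Hox genes, which mark the axial level of a ganglion, 1 was higher in proprioceptors than in each other subtype and 2 were lower. Hoxc8 stood at 29.4 ± 6.90 CPM in proprioceptors (n = 3), higher than in each other subtype (smallest log2 difference 2.12), and Hoxb5 at 3.22 ± 0.123 CPM, lower than in each (nearest -2.28). The proprioceptor ganglia were thoracic alone, and a candidate explanation is the absence of lumbar ganglia, which would lower Hox genes of paralog groups 10 to 13. 1 of the 6 tested genes of these groups was lower in proprioceptors than in each other subtype, Hoxd11, with at most 1 count per library, Hoxd10 was lower than in 5 subtypes, and Hoxa10 and Hoxc10 were lower than in none. A loss of these genes as a whole is argued against: their sum was 8.53 to 14.0 CPM in proprioceptor libraries against 2.78 to 21.8 CPM in the others, or 99.8% of the mean of the other subtypes (58.3% to 171% within 2 SE). Hoxa10 and Hoxc10 made up most of it. For Hoxd10 and Hoxd11, which lie near the floor, axial level and cell type cannot be told apart.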
